A study of Mus musculus with 16 samples.

How the data were processed

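RNA-seq was done on epididymal white adipose tissue (eWAT), the fat pad beside the epididymis, of mice 21 weeks old. The 16 libraries fall into 4 groups of 4 mice, made by genotype and diet. One diet was chow with 5% fat, and the other a high-fat diet (HFD) with 60% fat, fed from 5 weeks of age. The sample titles call the genotypes WT and KO, while the genotype field of the same samples says knockdown of ApoA4; the names KO and WT stand for the labels only. Per the labels, RNA was taken with TRIzol, libraries were made with an MGIEasy kit and sequenced as paired reads on a BGI-seq instrument, and the processing notes name STAR 2.7 and the genome builds GRCm38.p6 and mm10. The tool that made the expression values, its gene annotation, its filters and the strand of the libraries are not given in the sources used here.

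The deposited table holds FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library, computed by the authors and rounded to 2 decimals, for 20101 genes with Entrez numbers. Of these, 19945 matched the reference gene table by number and 156 did not, and 26 gene symbols that had been turned into dates were restored from the Entrez number. A further 14408 entries carry names of circular RNAs (mmu_circ_ and a number). Their values are whole multiples of 1 step per library, with 100% of those up to 100 steps within 0.05 of a step, so the authors scaled them to depth and not to length, by a constant that is not given in the sources used here. These entries were kept out of the gene comparisons.

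FPKM values carry no read counts, so the depth behind each gene's value is unknown and no counting interval is given. With 1 step taken as 1 read, the circular RNA entries put the relative depth of the libraries between 0.755 (chow KO replicate 4) and 1.43 (HFD KO replicate 4). Precision was read from the spread between the 4 mice of a group and from simulated data: of 100 genes given a true 2-fold change, limma recovered between 66% and 75% per 2-group comparison, and of 100 given a 4-fold change between 93% and 97%. It made 7 to 14 false calls among 12467 unchanged simulated genes. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2, and each gene was given independent noise. Structure that many genes of a library share is not in this simulation. The recovered shares and false calls thus do not carry over to genes of low value or to the real libraries as a whole.

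Genes with FPKM of at least 1 in at least 4 of the 16 libraries were tested, which left 12667 genes and put 7434 under the filter. Values were turned into log2(FPKM + 1) with a pseudocount of 1 and fitted with limma 3.58.1 in R 4.3.3, using 4 group means, all 16 libraries in 1 fit and empirical Bayes moderation with a variance trend. There were 5 comparisons: KO against WT on each diet, HFD against chow in each genotype, and the interaction, which is the KO minus WT difference on HFD less that on chow. A gene was said to change at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. Fold changes are log2 differences of group means with their SE, and group levels are FPKM as mean ± SD of 4 libraries.

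Lists of cell type markers and pathway genes, 33 in number with 644 members, were written before the data were examined, as were the comparisons, the filter, the thresholds, the genes to be named and most alternatives; 625 members had an entry. The 30 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, the rotation test fry, the number of members past the threshold over all genes, and the number past it when p was adjusted over the list alone. Genes named are Apoa4, 15 fixed genes of inflammation and adipocyte function, up to 10 genes with the largest rise and 10 with the largest fall per comparison among those past the threshold whose groups did not overlap (predicted genes and clone names left out), and up to 4 members with the smallest p of each list past the threshold. For the interaction they are up to 5 genes per direction with the smallest p. A gene named outside this rule is said to have been chosen after its values were seen.

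The alternatives were 3 other scalings (median-of-ratios size factors, a constant sum per library as in TPM, quantile normalization), pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, a replicate block, no variance trend, array weights, leaving out each library, the 2 groups compared alone, a 2-fold minimum and an adjusted p threshold of 0.1. Added after seeing the data were leaving out 2 or 3 libraries with epididymal genes, an epididymal score as a covariate and the circular RNA entries tested with the genes. Gene positions are from GENCODE and the reference gene table for GRCm38.p6. Some single genes, though their values stay in every fit and list, and a test by chromosome of the genes that differed on both diets are not reported here. Of 211 genes searched, 44 share an exon with a gene on the opposite strand and 17 with another gene on the same strand, so some of their reads can belong to the neighbour.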

Results

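Gene expression was measured by RNA-seq in epididymal white adipose tissue of 16 mice, 4 in each of 4 groups: chow WT, chow KO, HFD WT and HFD KO. The series asks what apolipoprotein A-IV, a lipid-binding plasma protein encoded by Apoa4, does to inflammation of white fat. Summed over genes, the deposited values ranged from 413167 FPKM (HFD WT replicate 1) to 468186 FPKM (chow WT replicate 1), and each library held between 11554 and 13184 genes at 1 FPKM or more. The lowest correlation between 2 libraries of a group, across genes on the log2 scale, was 0.986 in chow WT, 0.897 in chow KO, 0.909 in HFD WT and 0.855 in HFD KO. Diet was the main axis of the data: the first principal component held 58.1% of the variance, with chow libraries from −52.0 to −22.6 and HFD libraries from 6.06 to 76.8.

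Genes of the epididymis, the sperm duct that this fat pad lies against, were abundant in chow KO replicate 2 and HFD KO replicate 4. HFD KO replicate 2, counted with them below among the 3 libraries with epididymal genes, held few of them. Crisp1 and Spink8 (61.5 FPKM) were high in it, but Gpx5 was 2.97 FPKM, against at most 2.35 FPKM in the other 13 libraries. Gpx5, a glutathione peroxidase secreted by the epididymis, stood at 4187 FPKM in chow KO replicate 2, and Lcn9, an epididymal lipocalin, at 2788 FPKM. Crisp1, a protein that epididymal cells add to sperm, stood at 3799 FPKM in HFD KO replicate 4 and 276 FPKM in HFD KO replicate 2. The 20 listed genes of epididymis and testis took 3.64% of all FPKM in chow KO replicate 2, 1.20% in HFD KO replicate 4 and 0.0795% in HFD KO replicate 2, against at most 0.0121% in the other 13 libraries. The list itself, with 7 members above the filter, was not past the threshold in any comparison (camera adjusted p = 0.754 between genotypes on chow and 0.237 on HFD). The second principal component, with 15% of the variance, gave these libraries its highest scores, 66.5, 50.4 and 28.5.

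**Figure D1:**
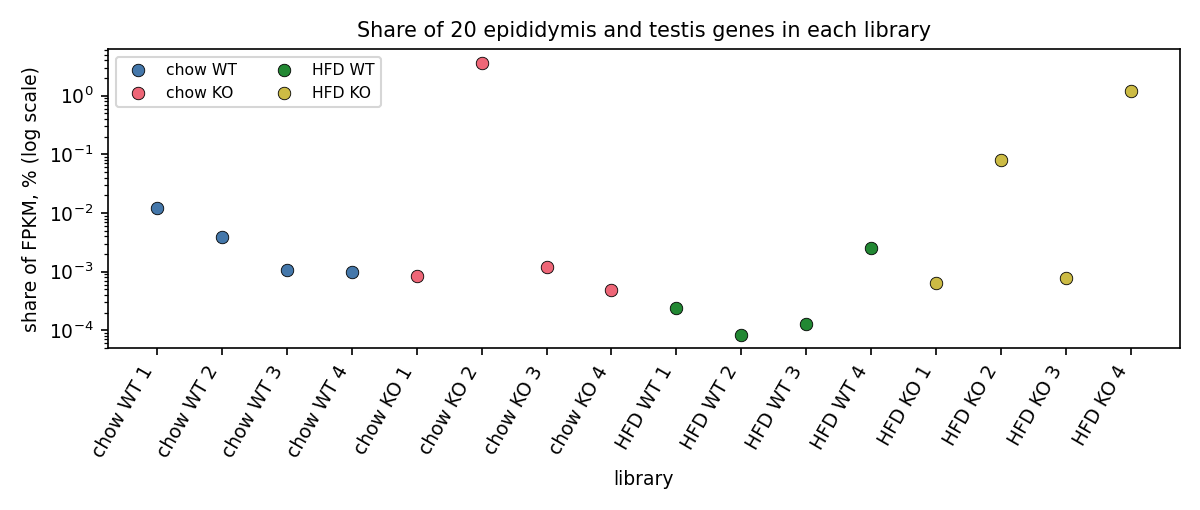
Share of FPKM taken by 20 genes of epididymis and testis in each of the 16 libraries, in percent on a log axis, with 1 point per library coloured by group. Chow KO replicate 2 (3.64%), HFD KO replicate 4 (1.20%) and HFD KO replicate 2 (0.0795%) lie above the other libraries, which reach at most 0.0121%.

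The targeted gene checks the genotype labels. Apoa4 RNA was higher, not lower, in the libraries labelled KO. On chow, Apoa4 stood at 0.29, 0.25, 0.23 and 0.09 FPKM in the libraries labelled WT and at 3.59, 1.96, 5.96 and 5.29 FPKM in those labelled KO. On HFD, the libraries labelled WT held 0.29, 0, 0.08 and 0 FPKM and those labelled KO 8.69, 9.63, 7.23 and 4.93 FPKM. Apoa4 (Entrez gene 11808, chromosome 9, 46240844 to 46243458 on GRCm38.p6) rose in the KO-labelled libraries by 2.03 on the log2 scale on chow (SE 0.24, adjusted p = 0.000476) and by 2.95 on HFD (SE 0.24, adjusted p = 4.04e-05). Its exons overlap 2 genes on the opposite strand, Gm10680 and Gm47528, and the strand of the libraries is not given in the sources used here, so reads of these genes can be part of the value. Apoc3, the neighbouring apolipoprotein gene, was chosen after its values were seen. It differed by 1.23 on chow (adjusted p = 0.131) and 1.74 on HFD (adjusted p = 0.165), short of the threshold. Every direction given for KO against WT rests on the labels, which the RNA of the targeted gene does not bear out as a loss of its transcript.

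The first question is what high-fat feeding did to the fat of WT-labelled mice. Genes of lipid-associated macrophages, which gather around dying adipocytes, rose the most. Gpnmb, a lysosomal glycoprotein of these cells, went from 9.78 ± 1.81 to 1351 ± 1079 FPKM (SD, n = 4; log2 change 6.49, adjusted p = 1.20e-05). Mmp12, the macrophage elastase, went from 12.5 ± 6.28 to 1530.2 ± 1616 FPKM, and Trem2, their lipid-sensing receptor, from 7.40 ± 1.55 to 232 ± 119 FPKM (adjusted p = 2.62e-06). Spp1 (osteopontin, log2 change 5.83), Atp6v0d2, a proton pump subunit (5.28), and Adam8, a leukocyte protease (5.02), rose as well. Of the 20 genes in the lipid-associated macrophage list, 18 rose and 0 fell (adjusted over the list alone, 18 rose and 1 fell; median log2 change 3.11, camera adjusted p = 1.19e-09), a call that ends with an estimated correlation, as does every list call of this comparison (smallest adjusted p = 0.630). Of the 20 general macrophage markers, 16 rose and 0 fell (median 2.06, adjusted p = 1.09e-05), among them Cd68, a macrophage lysosomal protein (3.15), Adgre1, which encodes F4/80 (2.73), and Tyrobp, the adaptor of Trem2 (2.53). Within HFD, the strength of this signature varied: Trem2 was 77.7 FPKM in HFD WT replicate 1 and 134 FPKM in HFD KO replicate 4, against 201 to 335 FPKM in the other 6 libraries.

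Inflammatory signals moved with the macrophage genes. Ccl2, the chemokine that recruits monocytes, rose from 2.38 ± 0.675 to 72.4 ± 42.1 FPKM (log2 change 4.31, adjusted p = 3.02e-05). Saa3, an acute-phase protein of fat (3.48), Ccl7, a monocyte chemokine (2.55), Nfkb2, an NF-kB subunit (1.26), and Tnf (1.27, adjusted p = 0.00325) rose, while Il1b differed by 0.34 (adjusted p = 0.714). Of 20 NF-kB target, cytokine and chemokine genes, 10 rose and 1 fell, over all genes and adjusted over the list alone (adjusted p = 0.0122). Lysosomal genes rose in 19 of 24 cases (median 1.22, adjusted p = 1.56e-06), with Ctss, a macrophage cathepsin, at 3.01 and Gla, alpha-galactosidase, at 2.74. Genes of the extracellular matrix rose in 18 of 24 cases and fell in 1 (adjusted p = 1.92e-05), with Col6a3, a collagen VI chain (2.16), and Tgfb1 (2.06). Of 20 cell cycle genes 19 rose (median 1.89, adjusted p = 2.90e-07), with Top2a, the topoisomerase of dividing cells, at 2.73 and Birc5 (survivin) at 2.93.

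Adipocyte genes went the other way. Cyp2e1, a cytochrome P450 abundant in lean fat, fell from 5027 ± 578 to 111 ± 78.3 FPKM (log2 change -6.27, adjusted p = 0.000672), and Cfd, the serine protease adipsin, from 7900.1 ± 793 to 227 ± 204 FPKM (adjusted p = 0.000165). Pck1, of glyceroneogenesis (-4.38), Pnpla2, the lipase ATGL (-2.08), Adrb3, the fat beta-adrenergic receptor (-2.91), Adipoq, adiponectin (-2.20), and Pparg, the regulator of adipocyte identity (-1.33), fell. Fam13a (-5.17), Agt, angiotensinogen (-4.42), Inmt (-5.17) and Acsm3 (-4.95) were among the 10 largest falls. Lep (1.10, adjusted p = 0.0924) and Slc2a4, the insulin-regulated glucose transporter (-0.88, adjusted p = 0.133), were not past the threshold. Of 22 adipocyte genes, 14 fell and 2 rose (median -1.31, adjusted p = 0.000114; 14 and 3 adjusted over the list alone). Genes of the TCA cycle and branched-chain amino acid breakdown fell in 20 of 26 cases (adjusted p = 1.70e-08), such as Ivd (-2.27) and Pccb (-1.84), and those of oxidative phosphorylation in 16 of 32 (median -0.46, adjusted p = 1.20e-05). Of 22 insulin signalling genes, 12 fell and 5 rose (adjusted p = 0.00498), with Irs1 (-1.63), Irs2 (-1.87) and the receptor gene Insr (-1.33) among those that fell. Within HFD WT the mean log2 score of this list was 4.45, 4.09, 4.12 and 4.48 in replicates 1 to 4. The adipocyte score was 8.71, 7.11, 6.85 and 8.20. The values are of whole tissue, here and in the KO-labelled mice. Lower expression within adipocytes and a smaller share of adipocyte RNA thus cannot be told apart. Mesothelial markers fell in 8 of 16 cases (adjusted p = 0.00474), such as Upk3b (-1.44). Cholesterol synthesis genes rose in 16 of 21 cases and fell in 1 (median 1.21, adjusted p = 8.73e-05), with Dhcr7, which makes cholesterol from its last precursor, at 2.37.

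In all, 5304 of 12667 genes changed with HFD in WT-labelled mice, 3121 higher and 2183 lower, 2059 of them at least 2-fold. The chow WT libraries stood apart from the 12 others, chow KO included, in some genes. Nnt, chosen after its values were seen, was at least 25.7 FPKM in chow WT and at most 10.6 FPKM elsewhere. In this comparison a trait of the chow WT group and the diet cannot be told apart for such genes. The scaling shifts this balance: 58.8% of changed genes were higher, against 51.3% with median-of-ratios scaling, 66.2% with a constant sum and 45.8% with quantile normalization, which moved the median of all genes by −0.104. Camera called 12 of 30 lists, 0 of them with an estimated correlation (smallest adjusted p = 0.630), while fry, which asks only whether members move one way, called 14.

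**Figure D2:**
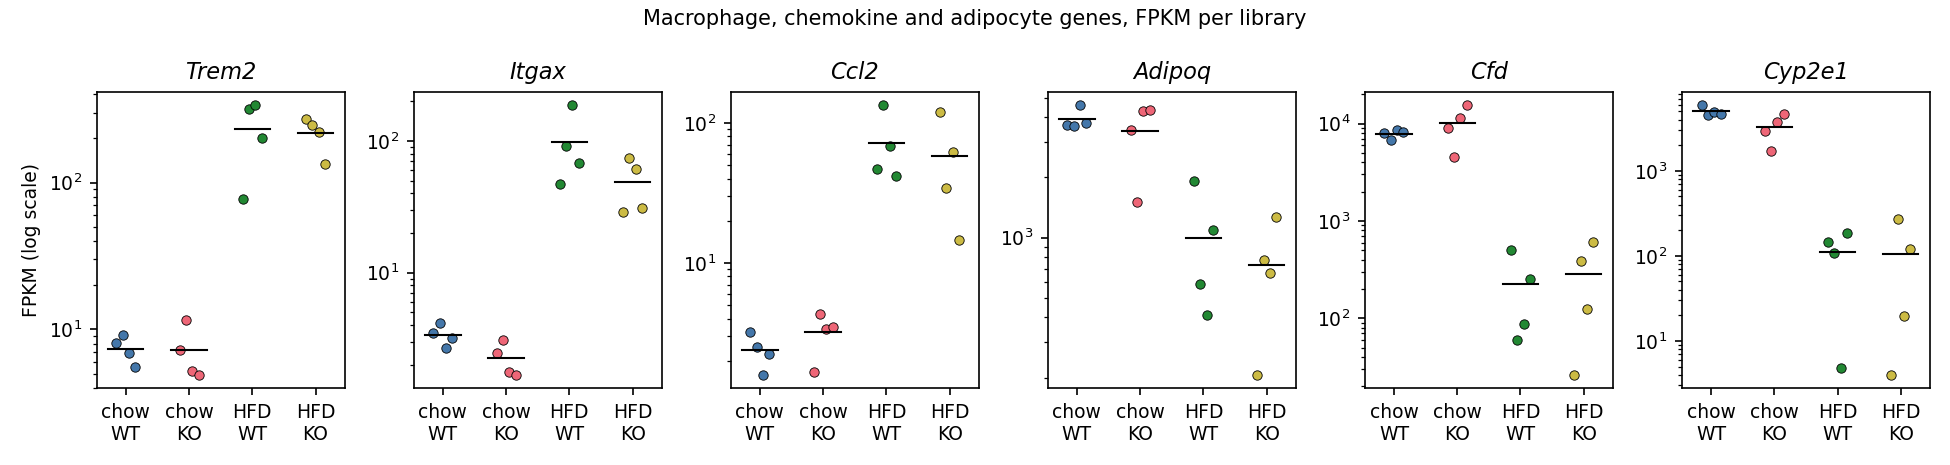
FPKM on a log axis of 6 genes in each library, by group, with points for libraries and a bar for the mean of 4. Trem2, Itgax and Ccl2 lie higher and Adipoq, Cfd and Cyp2e1 lower in the HFD libraries of both genotypes, as in Trem2 means of 7.40 and 232 FPKM in chow WT and HFD WT.

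The same question in the KO-labelled mice gave largely the same picture. Mmp12 rose from 4.24 ± 2.98 to 671 ± 433 FPKM (SD, n = 4; log2 change 6.91, adjusted p = 2.36e-05), Spp1 by 6.55, Gpnmb by 6.30, Trem2 by 4.76 and Lgals3, the macrophage lectin galectin-3, by 4.56. In chow KO replicate 2, which also holds the largest share of epididymal genes, Gpnmb (26.3 FPKM), Spp1 (13.8 FPKM) and Atp6v0d2 (34.3 FPKM) stood above the other chow KO libraries. Of the lipid-associated macrophage list 17 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 8.58e-10, a call that ends with an estimated correlation, like the other list calls here, at adjusted p of 0.498 or more), of the macrophage markers 17 rose (adjusted p = 1.42e-08), of the lysosomal genes 22 (adjusted p = 1.61e-09) and of the NF-kB and cytokine genes 14 (adjusted p = 2.08e-05). Ccl2 rose by 3.47, Saa3 by 4.15, Tnf by 1.43, Npy, neuropeptide Y, by 5.20 (3.71 without HFD KO replicate 4, which held 921 FPKM against 7.96 to 22.5 FPKM in the other 3) and Il1rn, the interleukin-1 receptor antagonist, by 4.34. Il1b rose by 1.78 (adjusted p = 0.0472), a call lost under each of the 3 other scalings and in 11 of the 12 fits without 1 library that test it. It rests on HFD KO replicates 1 (25.8 FPKM) and 3 (8.02 FPKM), against 1.46 and 0.18 FPKM in the other 2. Extracellular matrix genes rose in 19 of 24 cases (adjusted p = 1.36e-06), cell cycle genes in 19 of 20 (adjusted p = 3.91e-07) and immediate-early genes in 10 of 20 (adjusted p = 0.00299), with the stress-induced factor Atf3 at 3.76. Granulocyte and mast cell markers rose in 6 of 13 cases (adjusted p = 0.0165, lost without HFD KO replicate 1 or 3), such as S100a8, a neutrophil calcium-binding protein (2.88).

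Among genes that fell in the KO-labelled mice were Cyp2e1 (-6.15), Cfd (-5.77), Retn, resistin (-4.11), Adrb3 (-3.57), Adipoq (-2.37) and Slc2a4 (-1.89, adjusted p = 0.00516). Oxidative phosphorylation genes fell in 26 of 32 cases (median -0.77, adjusted p = 2.15e-12), TCA and branched-chain genes in 23 of 26 (adjusted p = 1.05e-11), adipocyte genes in 14 of 22 (adjusted p = 6.78e-08) and lipogenic genes in 11 of 19 (median -1.27, adjusted p = 2.03e-05), with Thrsp (-2.86) and Acaca, acetyl-CoA carboxylase (-2.78). Fatty acid oxidation genes fell in 8 of 20 cases and rose in 3 (adjusted p = 0.0170), insulin signalling genes fell in 7 of 22 and rose in 4 (adjusted p = 0.0300), interferon response genes fell in 4 of 19 (adjusted p = 0.00368), such as Ifit3 (-1.58), and mesothelial markers fell in 5 of 16 (adjusted p = 0.0355). The mesothelial call ends without 2 (adjusted p = 0.169) or 3 (0.0663) of the libraries with epididymal genes and with an epididymal covariate (0.0687). It also ends without chow KO replicate 2 (0.0529) or 4 (0.0526) or HFD KO replicate 3 (0.0507) or 4 (0.134) alone. The insulin signalling call ends with the covariate (0.0501) and without HFD KO replicate 4 (0.0655). The interferon response call ends without chow KO replicate 4 (adjusted p = 0.153), and that of fatty acid oxidation without chow KO replicate 3 or 4 or HFD KO replicate 1. In total 4922 genes changed, 2979 higher and 1943 lower. Of these, 60.5% were higher, against 49.8% with median-of-ratios scaling and 42.3% with quantile normalization, which moved the median of all genes by −0.149. Camera called 16 lists, 0 with an estimated correlation (smallest adjusted p = 0.498), and fry called 15.

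Across genes, which are not independent replicates, the diet effects in the 2 genotypes correlated with Pearson's r of 0.846 and Spearman's rho of 0.800. Both genotypes shared 2218 genes that rose and 1277 that fell, against 734 and 335 by chance, and 21 genes changed in opposite directions.

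The comparison the series is about is KO against WT on HFD. Few genes differed. Ppp1r3e, a subunit that targets protein phosphatase 1 to glycogen, fell from 5.04 ± 0.746 FPKM in the WT-labelled to 1.06 ± 0.359 FPKM in the KO-labelled libraries (SD, n = 4; log2 change -1.56, SE 0.14, adjusted p = 9.19e-05). Cdkn1b, which encodes the cell cycle inhibitor p27, rose from 9.76 ± 0.926 to 16.8 ± 2.09 FPKM (log2 change 0.72, adjusted p = 0.0370). With Apoa4 and the predicted gene Gm2427 (2.22, adjusted p = 0.00528; named because the count is small), these made 4 changed genes, 3 higher and 1 lower, of which 3 changed at least 2-fold; 1500 genes had an unadjusted p under 0.05. With median-of-ratios or quantile scaling, which move the median of all genes by −0.103 and −0.110, 4 genes are higher and 4 lower.

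None of the fixed genes of inflammation and adipocyte function passed the test between genotypes on HFD. Itgax, the CD11c marker of inflammatory fat macrophages, stood at 98.4 ± 61.2 FPKM in WT-labelled and 48.7 ± 22.4 FPKM in KO-labelled libraries (log2 difference -0.93, adjusted p = 0.361). Differences were 0.29 for Tnf, -0.54 for Ccl2, 1.64 for Il1b, -0.60 for Saa3, 0.03 for Cd68, -0.24 for Adgre1 and 0.06 for Trem2, with adjusted p from 0.376 (Il1b) to 0.988 (Cd68). The signs of Cd68 and Trem2 turn with median-of-ratios scaling, and that of Cd68 with a constant sum. Ccl2, Adgre1 and Saa3 turn positive without the 3 libraries with epididymal genes, a fit that keeps only HFD KO replicates 1 and 3. Lep differed by -1.11 (adjusted p = 0.413), Adipoq by -0.47, Slc2a4 by -0.26 and Pparg by -0.28. Il6, Nos2 and Ucp1 lay under the filter, with Il6 at most 1.42 FPKM in any library. The list of 26 IKK and JNK pathway components holds receptors and adaptors, such as Tlr4 and Myd88, beside the kinases that the series title names. It was not past the threshold (0 members changed, median 0.19, camera adjusted p = 0.104 on HFD and 0.305 on chow). Nor were the NF-kB target and cytokine genes (adjusted p = 0.472). RNA of the components does not measure the activity of the kinases, which was not tested.

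As groups, genes of cholesterol synthesis and oxidative phosphorylation were lower in the KO-labelled HFD libraries, with 0 members past the threshold over all genes, and only these 2 of 13 list calls hold whichever library is left out, none of the 13 with an estimated correlation. Their size still depends on single libraries: the difference of mean list scores shrinks from −0.599 to −0.377 without HFD KO replicate 1 for cholesterol synthesis, and from −0.148 to −0.0675 without HFD WT replicate 4 for oxidative phosphorylation. All 21 cholesterol synthesis genes had a negative log2 difference (median -0.60, camera adjusted p = 2.73e-14; adjusted p = 0.323 with an estimated correlation), and 2 were lower adjusted over the list alone. Dhcr7 stood at 19.6 ± 2.77 FPKM in WT-labelled and 10.4 ± 3.09 FPKM in KO-labelled libraries (adjusted p = 0.142). Camera called lower also oxidative phosphorylation (median -0.12, adjusted p = 6.29e-07), adipocyte genes (-0.31, adjusted p = 0.000174), lipid-associated macrophage genes (-0.31, adjusted p = 0.000287), extracellular matrix (-0.22, adjusted p = 0.000554), fatty acid oxidation (-0.12, adjusted p = 0.00191), TCA and branched-chain genes (-0.08, adjusted p = 0.00217), interferon response (-0.26, adjusted p = 0.00243), lipogenesis (-0.36, adjusted p = 0.00305) and endothelial markers (-0.11, adjusted p = 0.0471). It called higher granulocyte and mast cell markers (median 0.78, adjusted p = 0.00266), such as Mmp9 at 2.48 ± 1.83 and 9.29 ± 7.51 FPKM, T and NK cell markers (0.41, adjusted p = 0.0207) and B and plasma cell markers (0.59, adjusted p = 0.0253). With an estimated correlation the 13 calls all ended, the other 12 at adjusted p from 0.876 to 0.920, and fry called 0. HFD KO replicate 1 carries several calls. Without it those of adipocyte (adjusted p = 0.462), lipogenesis (0.462), fatty acid oxidation (0.350), TCA and branched-chain (0.772), granulocyte and B cell genes (0.254 for both) end. The difference of mean list scores then turns from −0.332 to 0.0995 for adipocyte genes and from −0.235 to 0.149 for lipogenesis. It turns from −0.106 to 0.102 for TCA and branched-chain genes and from −0.1496 to 0.0150 for fatty acid oxidation. It shrinks from 0.918 to 0.498 for granulocyte markers and from 0.606 to 0.399 for B and plasma cell markers. Adipoq (0.0407) and Slc2a4 (0.15) turn positive as well. The lipid-associated macrophage difference goes from −0.261 to −0.00788 without HFD WT replicate 3 and to 0.0106 without HFD KO replicate 4, and its call ends in each (adjusted p = 0.105 and 0.117). The matrix difference turns from −0.210 to 0.0693 without HFD KO replicate 4, where that call ends (0.597). Without HFD WT replicate 1 the adipocyte, lipogenesis, fatty acid oxidation and TCA calls end too. The endothelial call ends there as well (adjusted p = 0.848), and its difference turns from −0.108 to 0.137. Without HFD WT replicate 4 the endothelial difference turns to 0.04, and the call ends (adjusted p = 0.274).

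The KO-labelled HFD group holds 2 of the 3 libraries with epididymal genes, at 1.20% and 0.0795% of FPKM. Without all 3 the T and NK cell (adjusted p = 0.218), lipid-associated macrophage (0.117) and endothelial (0.861) calls end. The matrix list turns to higher (adjusted p = 0.0205), and 19 genes change. This fit keeps only HFD KO replicates 1 and 3, whose macrophage scores (7.25 and 6.88) exceed those of replicates 2 and 4 (6.22 and 5.47). Epididymal genes and macrophage content thus cannot be told apart in it. The T and NK cell call also ends without HFD KO replicate 4 alone (adjusted p = 0.336) or HFD WT replicate 2 (0.0642). Its difference of mean list scores falls from 0.342 to 0.186 without HFD KO replicate 4. With an epididymal covariate the interferon response call ends (adjusted p = 0.586). The count of changed genes is 9 without chow KO replicate 2 and 10 without HFD KO replicate 3. It is 0 among genes with a mean FPKM of at least 5. The Cdkn1b call ends without any 1 of 13 libraries and without the epididymal libraries, while Apoa4 and Ppp1r3e stay past the threshold in each of these fits that tests them.

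On chow, without the high-fat challenge, more genes differed by label. Thbs1, which encodes the matrix protein thrombospondin-1, fell from 384 ± 78.1 FPKM in WT-labelled to 17.9 ± 15.1 FPKM in KO-labelled libraries (SD, n = 4; log2 change -4.74, SE 0.48, adjusted p = 0.000152). Eif4ebp3, a repressor of cap-dependent translation, fell from 86.2 ± 19.9 to 6.37 ± 0.728 FPKM (adjusted p = 1.69e-08), and Pdk4, the kinase that slows glucose oxidation in fasting, from 124 ± 27.3 to 17.9 ± 10.8 FPKM (adjusted p = 0.00223). The lipogenic enzymes Elovl6, a fatty acid elongase (1.75 ± 0.306 to 22.9 ± 14.4 FPKM, adjusted p = 0.0464), and Acly, ATP citrate lyase (44.0 ± 3.13 to 202 ± 130.1 FPKM, adjusted p = 0.0166), rose. Elovl6 was 2.51 FPKM in chow KO replicate 1 and 22.9 to 33.5 FPKM in the other 3, and its call ends under 12 of the 16 fits that leave out 1 library. Exons of Thbs1, Elovl6 and Hpca overlap genes on the opposite strand (Gm29233, Gm35986 and Tmem54) and those of Eif4ebp3 a gene on the same strand, so reads of the neighbours can be part of these values.

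Lrmda, a melanocyte differentiation gene, rose from 1.09 ± 0.158 to 13.4 ± 3.23 FPKM (adjusted p = 1.08e-05). Cdkn2c, an inhibitor of CDK4 and CDK6 (1.31), Nrep (1.49), H2-T24 (1.16), Hpca (1.10) and Rhbdl3 (0.97) rose as well. The actin genes Acta1 (-4.42) and Acta2 (-2.77), the Wnt antagonist Sfrp5 (-2.90), the imprinted gene Peg10 (-2.39), the small heat shock gene Hspb7 (-2.38) and the major urinary protein genes Mup14 (-2.69) and Mup15 (-3.08), whose reads can be shared within their family, fell. Ppp1r3e fell here too, from 5.77 ± 0.553 to 1.49 ± 0.296 FPKM, and Nnt, a mitochondrial transhydrogenase chosen after its values were seen, from 27.3 ± 1.78 to 7.66 ± 0.778 FPKM.

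By list, genes of interferon response and lipid synthesis were higher and macrophage and matrix genes lower in chow KO with camera's preset correlation. None of these calls holds with an estimated correlation (adjusted p = 0.806 for each of 10), and fry called 0. All 19 interferon response genes had a positive difference with 0 past the threshold over all genes and 1 adjusted over the list alone (median 0.76, camera adjusted p = 1.88e-05); Cmpk2 stood at 1.77 ± 0.731 and 6.08 ± 3.44 FPKM (adjusted p = 0.0569) and Ifit3 at 7.81 ± 2.30 and 31.1 ± 28.0 FPKM. The difference rests on 2 of the 4 KO-labelled libraries: the mean log2 score of the list was 3.90 and 4.80 in chow KO replicates 3 and 4, but 2.65 and 2.68 in replicates 1 and 2, within the chow WT range of 2.34 to 2.98. Of 19 lipogenic genes 2 rose, Elovl6 and Acly, and 7 adjusted over the list alone (median 1.06, adjusted p = 5.71e-05), and cholesterol synthesis genes had a median of 0.61 (adjusted p = 0.000854; 0 passed). Lower were the lists of lysosome (adjusted p = 0.000235; Gaa, acid alpha-glucosidase, fell by 0.62, the only 1 of 24 members to pass), extracellular matrix (adjusted p = 0.000569), macrophage (-0.38, adjusted p = 0.00164), endothelial (-0.22, adjusted p = 0.00390), immediate-early (adjusted p = 0.00536), dendritic and MHC class II (adjusted p = 0.0144) and lipid-associated macrophage genes (adjusted p = 0.0276), with 0 members passing in these 6. The endothelial call ends without 2 (adjusted p = 0.0563) or 3 (0.0669) of the libraries with epididymal genes, and that of lipid-associated macrophage genes with an epididymal covariate (0.0759). The endothelial, immediate-early and dendritic calls end without chow KO replicate 3 (adjusted p = 0.0580, 0.0641 and 0.0641) and the lipid-associated macrophage call without chow KO replicate 1 (0.0922) or chow WT replicate 2 or 3. None of the fixed genes passed the test, with Saa3 at -1.27 (adjusted p = 0.331) and Tnf at 0.14.

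On chow 178 genes changed, 54 higher and 124 lower, 87 of them at least 2-fold. Of these 30.3% were higher, against 19.2% with median-of-ratios scaling. The count is 90, 55, 79 and 61 without chow WT replicates 1, 2, 3 and 4 and 87 without chow KO replicate 1. Chow KO replicate 2 is the only 1 of the 3 libraries with epididymal genes in this comparison. Without it alone the count is 121, and 96 of the 178 calls stay. The count is 188 without 2 and 240 without all 3 of these libraries. The HFD libraries among them enter this comparison only through the filter and the shared estimate of the spread.

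**Figure D3:**
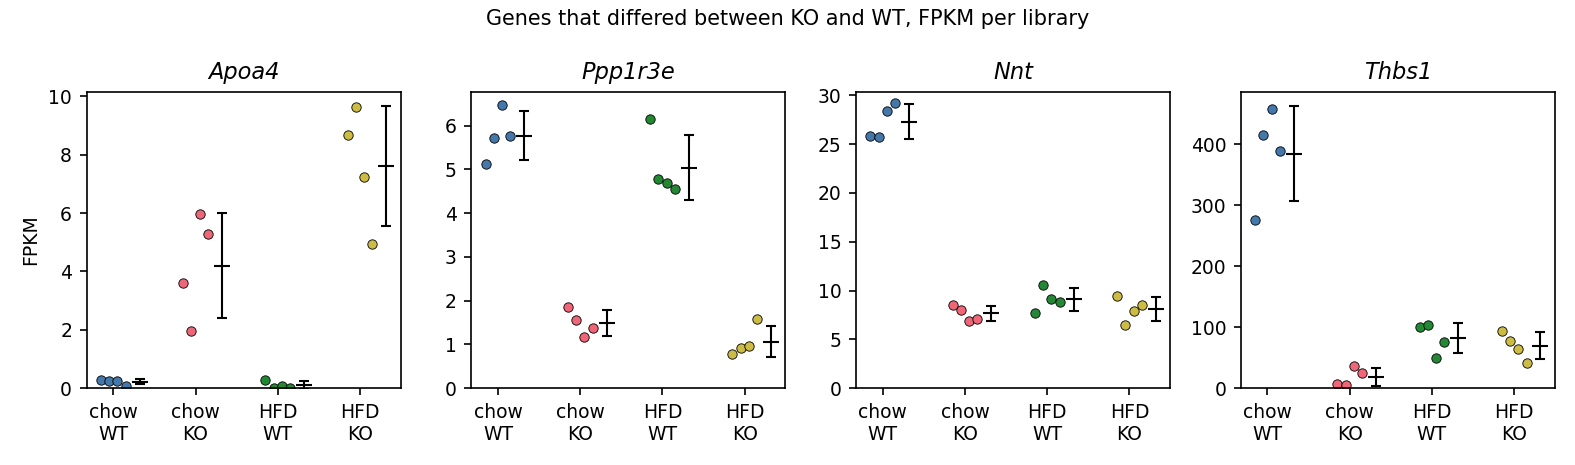
FPKM of 4 genes per library, by group, with points for libraries and a bar with whiskers for the mean and SD of 4. Apoa4 is higher and Ppp1r3e lower in the libraries labelled KO on both diets, while Nnt and Thbs1 are higher in chow WT (Nnt mean 27.3 FPKM) than in the other 3 groups (Nnt means 7.66, 9.09 and 8.09 FPKM).

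The genotype effects on the 2 diets had little in common across genes, with Spearman's rho of 0.144 and Pearson's r of 0.186. With 1 library left out rho ran from −0.053 to 0.207 (jackknife SE 0.226), so its sign is not settled. They shared 3 genes: Apoa4 and Gm2427 rose and Ppp1r3e fell on both diets, against 0.0128 and 0.00979 genes by chance. Over the 3121 genes that HFD raised in WT-labelled mice, the mean KO minus WT difference was 0.12 on chow and −0.01 on HFD, and over the 2183 it lowered −0.17 and 0.13. The WT libraries enter both sides of these means, and unchanged simulated groups gave 0.04 and −0.05 on chow and −0.04 and 0.05 on HFD. When the 4 shared WT libraries were split 2 and 2, the chow means kept their sign (0.12 to 0.16 and −0.21 to −0.14), while those on HFD ran from −0.14 to 0.28 and from −0.13 to 0.33. The chow mean over raised genes fell to 0.0451 without chow KO replicate 2, which holds epididymal genes, and to 0.0547 with median-of-ratios scaling, within and just above the simulated range of 0.0315 to 0.0541. Its excess over no change thus rests on that library and on the scaling. The mean over lowered genes was −0.127 and −0.208 in these fits, against a simulated −0.0655 to −0.0338. The jackknife SE over libraries is 0.108 for the raised and 0.0806 for the lowered genes, wide beside the simulated ranges, so neither mean is set apart from no change.

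The interaction asks whether the genotype effect differs between the diets. The 5 genes with the smallest p among positive interactions were highest in chow WT. Eif4ebp3 had an interaction of 3.61 on the log2 scale (SE 0.23, adjusted p = 1.85e-06), with 86.2 ± 19.9 FPKM in chow WT and 6.37 ± 0.728, 3.33 ± 0.936 and 3.46 ± 0.214 FPKM in chow KO, HFD WT and HFD KO (SD, n = 4). Nnt (1.56, adjusted p = 0.00102), Arrdc3, an arrestin-like regulator of adrenergic receptors (2.55; 122 FPKM in chow WT and 17.6 in HFD WT), Enc1 (1.66) and Atoh8 (1.73) followed. In the other direction were Lrmda (-2.71), the interferon-induced Ifi35 (-1.09), Dhcr7 (-1.38), Ano8 (-0.77) and Timm8a1 (-1.15). Cholesterol synthesis genes were lower as a list (median -1.28, camera adjusted p = 3.33e-15; 1 of 21 passed, and 14 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). So were interferon response (-1.01, adjusted p = 4.81e-09), lipogenesis (-1.30, adjusted p = 2.71e-08) and oxidative phosphorylation genes (-0.25, adjusted p = 1.57e-05), while immediate-early genes (0.33, adjusted p = 0.00642; Hspa1a passed), T and NK cell markers (0.48, adjusted p = 0.0144) and dendritic and MHC class II genes (0.43, adjusted p = 0.0188, lost without any 1 of 4 libraries) were higher. With an estimated correlation 0 of these 7 calls hold, the other 6 at adjusted p from 0.755 to 0.869, and fry called 0. In total 37 genes passed, 32 higher and 5 lower (86.5% higher, against 72.7% with median-of-ratios scaling and 73.7% with quantile normalization). The count is 21, 13, 15 and 12 without chow WT replicates 1, 2, 3 and 4.

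**Figure D4:**
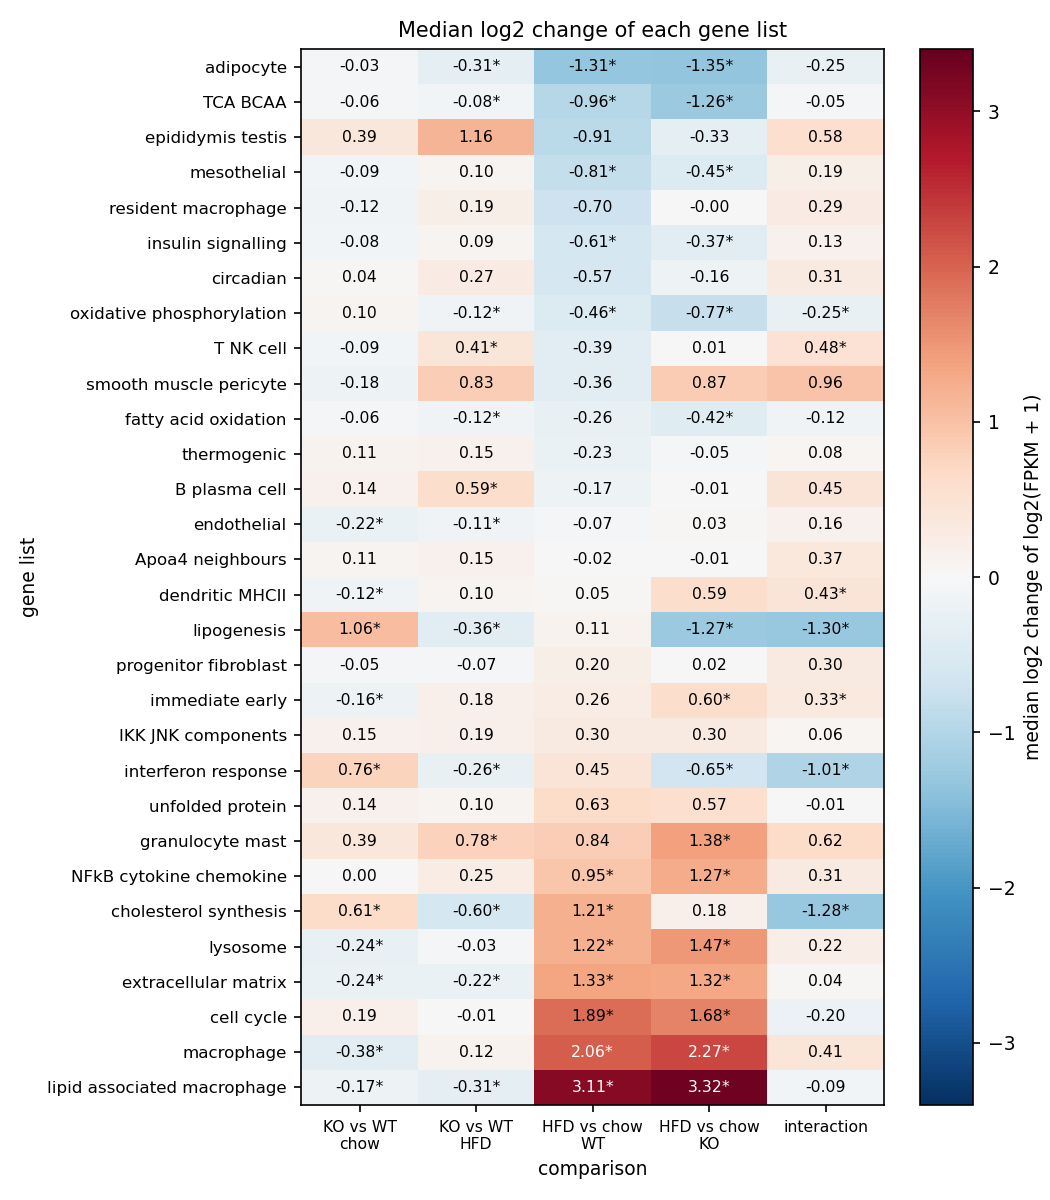
Median log2 difference of the tested members of 30 gene lists in 5 comparisons, as a colour scale from blue (lower) to red (higher) with the value in each cell and an asterisk for a camera adjusted p under 0.05 at the preset correlation. Lipid-associated macrophage genes have medians of 3.11 and 3.32 under HFD, and adipocyte genes -1.31 and -1.35, while medians between genotypes lie between −0.60 and 1.16.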

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

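The tests on epididymal genes, on Apoa4, on the clock genes and on Nnt were chosen after the results were seen, while the test of 15 fasting and glucocorticoid genes and the counts over other splits of the libraries were set out before their results were seen.

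Genes of the epididymis took 3.64% of FPKM in chow KO replicate 2, 1.20% in HFD KO replicate 4 and 0.0795% in HFD KO replicate 2. An effect of the genotype is argued against, because 5 libraries labelled KO lie below the highest library labelled WT (0.0121%). Reads carried over from 1 source library are argued against as well, because the ratio of Gpx5 to Crisp1 spans a 353000-fold range over the 3 libraries, from 23.2 in chow KO replicate 2 to 6.58e-05 in HFD KO replicate 4. Epididymal tissue in the dissected fat is a candidate source: 18 of the 20 listed genes, of which 7 pass the expression filter, stood at 10 times or more the highest other library in at least 1 of the 3. Genes at 50 FPKM or more and at least 100 times the other libraries numbered 39 in chow KO replicate 2 (led by Gpx5, Lcn9, Defb25 and Lcn8). HFD KO replicate 4 held 25 (led by Crisp1 and Spink8) and HFD KO replicate 2 held 9. Of these, 11, 2 and 0 were in the epididymis and testis list. Those of HFD KO replicate 2 include Svs2, Svs4 and Svs5, which encode seminal vesicle proteins. Epididymal tissue as a candidate thus rests on the other 2 libraries.

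Apoa4 stood at 1.96 to 9.63 FPKM in the libraries labelled KO and at 0 to 0.29 FPKM in those labelled WT. Epididymal tissue is argued against as the source, since the lowest of the 5 KO-labelled libraries without epididymal genes, at 3.59 FPKM, lies above every WT-labelled library. Single libraries under the wrong genotype are argued against, since 0 libraries lie in the range of the other genotype. An exchange of the genotype names as a whole stays open: the lowest KO-labelled library exceeds the highest WT-labelled one by 1.67 FPKM, as an exchange would need, but the name and the group cannot be told apart from the RNA alone. An altered allele that still makes, or makes more of, its transcript without its protein stays open too, as do reads of the overlapping opposite-strand genes Gm47528 and Gm10680, and neither was tested.

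The 4 chow WT libraries stood apart from the other 12 in genes such as Eif4ebp3, Thbs1 and Nnt. Feeding state or glucocorticoids at collection may contribute to the difference from chow KO: 15 further genes raised by fasting or glucocorticoids were lower in chow KO than in chow WT as a set (camera p = 0.000412, or 0.0262 with an estimated correlation), with a median log2 difference of −0.26, 10 of 15 negative, and Mt1 and Txnip past the threshold. Whether it reaches to the difference from HFD WT stays open: in HFD WT against chow WT the same set had a median of −0.50, 9 of 15 negative, 6 lower and 3 higher past the threshold, and camera p = 0.0783 (0.230 with an estimated correlation). The hour of collection stays open, since clock genes of the 2 opposite arms differed by 0.285 on the log2 scale with an SE of 0.538. Between genotypes on HFD, where no chow library enters, the arms differed by −0.911 with an SE of 0.409. A different substrain of the chow WT mice stays open, since Nnt, which is damaged in some C57BL/6 substrains, was at least 25.7 FPKM in chow WT and at most 10.6 FPKM in the other 12 libraries, a gap of 15.1 FPKM. The strain is not given in the sources used here, all 4 libraries of the group share the pattern, and an effect of the genotype on chow stays open and untested beside these, so they cannot be told apart.

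Other splits of the same libraries show which counts exceed those of arbitrary groups. On chow, 1 of 35 splits, the real one, gave as many genes as the 178 between genotypes, and the highest other gave 0. A rank of 1 in 35 is the most that such splits can reach. The other splits also carry the real group difference in their spread, which lowers their counts. The real grouping thus stands out, but chance is not excluded. On HFD, 7 of 35 splits gave at least 4 genes, so chance is not excluded. The highest other split gave 3139 genes, with HFD WT replicates 1 and 4 and HFD KO replicates 2 and 4 on 1 side. This points to a structure of the HFD libraries across genotypes. The mean log2 macrophage score was 5.41 to 6.22 in these libraries and 6.82 to 7.25 in the other HFD libraries. The adipocyte score was 7.805 to 8.71 in these and 6.09 to 7.499 in the others. Both genotypes lie on each side, so this difference is part of the spread within each HFD group. It can lower the count between genotypes on HFD. For the diet effect, 1 of 35 splits gave as many genes in WT (5304, highest other 0) and 1 of 35 in KO (4922, highest other 2246). The highest other split in KO had chow KO replicates 1, 3 and 4 and HFD KO replicate 4 on 1 side. The real grouping stands out in both, under the same limits as on chow. For the interaction, 6 of 100 drawn splits gave at least 37 genes, the highest other 1179, so chance is not excluded.

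Single libraries lay far from the other 3 of their group in 54 of 968 groups tested, or 5.58%, where chance marks about 1 in 20: in 3 of 24 groups for library measures, 8 of 120 for list scores and 43 of 824 for named genes. Chow KO replicate 2 had the most. Its epididymal share was 3.64% of FPKM, and its mean log2 scores were 5.59 for the epididymis and testis list, 4.91 for lipid-associated macrophage genes (high) and 5.53 for fatty acid oxidation (low). In FPKM it was high in Gpnmb (26.3), Spp1 (13.8), Atp6v0d2 (34.3), Kit (7.48), Fdps (21.1) and Adgrg2 (239.8). It was low in Lrmda (8.51), Emilin2 (12.9), Pnpla3 (23.8), Pnpla2 (494), Hibch (45.5), Trib3 (2.74), Eci1 (79.1) and Mup14 (0). HFD KO replicate 1 was low in Pparg (29.5 FPKM), Pnpla3 (1.51), Me1 (41.6), Idh3a (29.1), Acaca (10.9) and Enc1 (10.2) and high in Cd79b (7.18). HFD KO replicate 4 was low in the lipid-associated macrophage score (6.81) and Ctsz (213 FPKM) and high in Mup15 (1.22), Mup14 (4.72) and Fcrla (2.12).

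HFD WT replicate 1 was low in the interferon response score (2.46) and high in Mup14 (2.26 FPKM), Ppp1r3e (6.15), Col6a2 (399) and Col6a1 (348). HFD WT replicate 3 was high in Saa3 (388 FPKM) and low in Cyp2e1 (4.84), and HFD WT replicate 4 was high in epididymal share (0.00252%) and the circadian score (2.95). Chow KO replicate 1 was low in Elovl6 (2.51 FPKM) and Nfkb2 (8.50) and high in Dgat2 (714) and the insulin signalling score (4.94). Chow WT replicate 1 held 12102 genes at 1 FPKM or more and was high in the NF-kB and cytokine score (2.34), Stat2 (8.53 FPKM) and Npy (1.90) and low in Pnpla2 (1516). Chow WT replicate 3 was high in Adipoq (4573 FPKM) and low in Sqle (1.69) and Dusp1 (25.4). Chow WT replicate 2 was high in Cidec (2998 FPKM) and low in Bcat2 (50.6), and chow WT replicate 4 was low in Il1rn (0.58).

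The genotype effect differed between diets by the interaction test for 13 named genes. The log2 values were 3.61 for Eif4ebp3, 4.48 for Thbs1, 2.55 for Arrdc3, 2.34 for the heat shock gene Hspa1a, 1.73 for Atoh8, 1.66 for Enc1, 1.56 for Nnt and 0.83 for Cdkn1b, and −2.71 for Lrmda, −1.38 for Dhcr7, −1.15 for Timm8a1, −1.09 for Ifi35 and −0.77 for Ano8. Among lists, camera adjusted p was 3.33e-15 for cholesterol synthesis, 2.71e-08 for lipogenesis, 4.81e-09 for interferon response and 1.57e-05 for oxidative phosphorylation, all lower, and 0.00642 for immediate-early genes, 0.0144 for T and NK cell markers and 0.0188 for dendritic and MHC class II genes, all higher. All 7 calls end with an estimated correlation (smallest adjusted p = 0.271), fry called 0, and that of T and NK cell markers also ends without 2 of the libraries with epididymal genes (adjusted p = 0.0574).

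The circular RNA entries, used in no comparison of genes, held signals of their own among 8344 tested with limma. Between genotypes 10 differed on chow and 4 on HFD, and between diets 894 in WT and 1227 in KO. For the interaction 0 passed, with 625 at an unadjusted p under 0.05. Chosen after their values were seen, mmu_circ_0000534 went from 1942 ± 369 in chow WT to 4.81 ± 2.36 in chow KO and from 1677 ± 528 in HFD WT to 0.8285 ± 0.693 in HFD KO (adjusted p = 3.95e-19 and 3.89e-21), in depth-scaled units with an unknown constant. The entry mmu_circ_0005263 went from 13230.1 ± 2242 to 2391 ± 692 on chow and from 9928 ± 2962 to 1481 ± 609 on HFD.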

How the results depend on the processing

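Leaving out the 2 or 3 libraries with epididymal genes, the epididymal covariate and the fits with circular RNA entries were chosen after seeing the data. The diet effects were the most stable: the counts of 5304 and 4922 genes stayed within 1.5 times under every scaling, pseudocount and filter and every library left out, and 3627 or more of the KO calls and 4083 or more of the WT calls were shared, in the same direction, when any 1 library was left out. Across the other settings and libraries left out, named genes kept their direction and side of the threshold in 7952 cases, fell short of it in 235, passed it anew in 52 and reversed in 29. What depth limits cannot be said from FPKM, which carries no counts.

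The 178 genes between genotypes on chow became 115 with a replicate block, 1156 with array weights, 357 with only the 2 groups compared, 87 at 2-fold or more and 365 at an adjusted p threshold of 0.1. Replicate numbers gave no sign that they pair the mice. The correlation of same-numbered libraries ran from −0.63 to 0.37, and the best match was the own number in 4 of 16 cases. Such correlations cannot exclude a pairing, and the replicate block is given only here. The 4 genes on HFD became 8 with median-of-ratios and 8 with quantile scaling, 10 with array weights, 19 without the 3 libraries, 12 with the circular RNA entries, 2 with only the 2 groups, 7 at a threshold of 0.1 and 0 at a mean FPKM of at least 5, a filter that leaves out Apoa4 and Ppp1r3e. The 37 interaction genes became 18 with a replicate block, 418 with array weights, 66 with the epididymal covariate and 66 at a threshold of 0.1. At 2-fold or more, HFD changed 2059 genes in WT and 1938 in KO, and array weights gave 7496 in KO. Apart from the filters and thresholds, the cause was not tested.

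Leaving out 1 library at a time gave 55 to 230 genes on chow, 3 to 10 on HFD and 12 to 46 for the interaction, with the low chow counts without chow WT replicates 1 to 4 (90, 55, 79 and 61) and chow KO replicate 1 (87), the high HFD counts without chow KO replicate 2 (9) and HFD KO replicate 3 (10), and the low interaction counts without chow WT replicates 1 to 4 (21, 13, 15 and 12). Apoa4 rose with HFD in KO-labelled mice by 0.77, a call which fell short of the threshold at 0.67 with median-of-ratios scaling, 0.62 with quantile scaling, 0.92 with a pseudocount of 0.1 and 0.77 with only the 2 groups, and ran from 0.52 to 0.94 with 1 library out, short of it without HFD KO replicate 1 (0.70) or 2 (0.66).

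Of camera's lists, 0 were called with an estimated correlation in any of the 5 comparisons. Fry called 0 between genotypes on chow, 0 on HFD and 0 for the interaction. The mixed test of fry, which asks for change in either direction, called 3, 1 and 2 lists in these comparisons. The 7 interaction lists became 13 without 2 libraries, 17 without 3 and 13 with the covariate, and 6 to 16 with 1 library out. The matrix list on HFD turned to higher without the 3 libraries (adjusted p = 0.0205) and, short of the threshold, with the covariate (0.943), and its call ended without the 2 libraries, and the endothelial list on HFD ran from 3.29e-05 to 0.848 with 1 library out. The genotype effects on the 2 diets shared 0 genes at a mean FPKM of at least 5, as they must, since that filter leaves 0 changed genes on HFD. They shared 5 without the 3 libraries. Without those 3, the mean KO minus WT difference on HFD was 0.20 over genes raised by HFD in WT and −0.0846 over genes lowered, and on chow 0.0421, within the range of simulated unchanged groups, and −0.121.

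Signs of genes that did not pass between genotypes turned in places. On chow, Adipoq was 0.0131 with array weights and 0.0424 without the 2 or 3 libraries, and Pparg 0.0410 with quantile scaling and 0.0201 without the 2 or 3 libraries. On HFD, Cd68 was −0.10 with median-of-ratios scaling and −0.00322 with a constant sum, and Trem2 −0.0573 with median-of-ratios scaling, −0.19 with array weights and −0.00752 with the covariate. Adgre1 was 0.12 without 2 libraries, 0.29 without 3 and 0.0443 with the covariate. Without 3 libraries Ccl2 was 0.40, Saa3 0.38 and Fabp5 0.0528. With array weights Pparg was 0.0433, Ptprb 0.16 and Col4a2 0.000648. Il1b between diets in WT was −0.0177 with the covariate. With 1 library out, on chow Trem2 ran from −0.31 to 0.0524, Adipoq from −0.46 to 0.0424 and Pparg from −0.28 to 0.0244, and on HFD Tnf from −0.0222 to 0.47, Adgre1 from −0.65 to 0.12, Cd68 from −0.42 to 0.38, Trem2 from −0.39 to 0.31, Adipoq from −0.83 to 0.0407 and Slc2a4 from −0.59 to 0.15. No called list changed direction with median-of-ratios scaling, the only other scaling under which the lists were tested.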

Other observations

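The genes that differed on both diets and the circular RNAs were singled out after their values were seen. So were Hspa5, Asns, Nr1d1, Per1, Ikbke and Tlr2, which come from lists without a call. Resident macrophage markers did not move with the other macrophage genes under HFD. In WT-labelled mice 3 of 15 rose and 6 fell (camera adjusted p = 0.0541) and in KO-labelled mice 3 rose and 5 fell (adjusted p = 0.441). Retnla, a product of alternatively activated macrophages, fell by 3.95 in KO, and, chosen after their values were seen, Timd4, a receptor of long-lived resident macrophages, fell by 1.40 in WT and 1.82 in KO, while Mrc1, the mannose receptor CD206, rose by 1.14 and 1.42. Genes of the unfolded protein response rose in 11 of 20 cases and fell in 4 in WT (adjusted p = 0.194) and rose in 10 and fell in 2 in KO (adjusted p = 0.0922), with the chaperone Hspa5 at 1.27 and 1.02 and Asns, asparagine synthetase, at -2.23 and -1.59. Circadian genes fell in 6 of 18 cases and rose in 1 in WT (adjusted p = 0.0541), with Nr1d1 (REV-ERB alpha) at -1.71 and Per1 at -1.83, and fell in 1 in KO (adjusted p = 0.0922). Among components of the IKK and JNK pathways, 9 of 26 rose and 3 fell in WT (adjusted p = 0.436) and 8 rose and 4 fell in KO (adjusted p = 0.371), with Ikbke, an IKK-related kinase, at 1.29 and 1.56 and Tlr2 at 1.15 and 1.07.

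Other lists gave no call in most comparisons. Thermogenic genes had adjusted p of 0.330 on chow, where Pdk4 fell and the median (0.11) and the test differ in sign, and 0.717 on HFD; Ucp1, the uncoupling protein of brown fat, was 67.2 FPKM in HFD KO replicate 2 and at most 2.10 FPKM in the other libraries. Smooth muscle and pericyte markers had adjusted p of 0.124 and 0.282 between genotypes, progenitor and fibroblast markers 0.0915 and 0.237, mesothelial markers 0.140 and 0.859, insulin signalling genes 0.0630 and 0.901 and cell cycle genes 0.475 and 0.472. Resident macrophage markers had 0.0915 and 0.508, and B and plasma cell markers 0.402 on chow. Between diets, adjusted p in WT and in KO was 0.154 and 0.907 for T and NK cell markers, 0.723 and 0.840 for B and plasma cell markers, 0.436 and 0.771 for thermogenic genes, 0.792 and 0.201 for smooth muscle and 0.901 and 0.785 for progenitor and fibroblast markers. Skeletal muscle markers had 2 tested members and pancreatic acinar markers 1, too few for a test, and the mitochondrially encoded list had no entry in the table. Genes near Apoa4 had camera adjusted p of 0.686 on chow and 0.5681 on HFD. The mixed test of fry, which asks for change in either direction, gave 0.0404 and 7.99e-05. On HFD 4 of 13 were higher and 1 lower adjusted over the list alone. The mean log2 score of the list was 3.79 and 3.67 in HFD KO replicates 2 and 4, counted among the libraries with epididymal genes. It was 3.35 and 3.39 in HFD KO replicates 1 and 3 and 3.21 to 3.35 in HFD WT. The list shares Tagln with the smooth muscle list, whose score was 5.69 in HFD KO replicate 2.

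The genotypes differed in the same direction on both diets at an unadjusted p under 0.01 for 26 genes, a set read from the data. Among them Pnp2, Ang, Prmt5 and Ppp1r3e were lower and Apoa4, Apoc3, Ccdc82 and Ubp1 higher in the libraries labelled KO. Mt2, a metallothionein, was also in the set, at -1.72 on chow (adjusted p = 0.0106) and -1.07 on HFD (adjusted p = 0.302). Some of the circular RNA entries were also higher on chow in the libraries labelled KO, such as mmu_circ_0000537, at 58.5 ± 7.80 in chow WT and 169 ± 25.1 in chow KO (SD of 4 libraries, limma adjusted p = 0.00742).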
